A study of Rattus norvegicus with 6 samples.

How the data were processed

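Samples of left ventricular myocardium from male rats, 6 in all, were profiled on Agilent single-colour rat miRNA arrays, 3 from controls operated on without ligation and 3 from rats 24 h after ligation of the left coronary artery. Total RNA was extracted with TRIzol, per the labels. Groups were taken from the time in each sample's title. The arrays were scanned and the spots quantified with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, and each array carried 12128 spots for 1806 probes, with a median of 8 spots per probe. Per the file headers, the spot values are intensity values on a linear scale, with the background already subtracted in the processed signal, and the software's total signal per miRNA is set to 0.1 where the miRNA was not detected. Other columns deposited are flags for outlier spots, for spots well above background and for detected miRNAs, 0 or 1 per the file headers. The authors' processed values are on a log2 scale. The column medians are all 3.95 and the upper quartiles all 7.04, as after quantile normalization, and each column follows the ranks of that array's software total signal (Spearman's rho at least 0.9999). Between 244 and 288 of their 780 features sit at the lowest value of the array, which is not the same on every array.

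Spots flagged as outliers, between 8.32% and 9.63% per array, were left out, and the spots of each probe were averaged. No spot was saturated. A probe was taken as detected where over 50% of its spots were well above background, and a miRNA where any of its probes was. Each array was scaled to the 75th percentile of the 885 probes detected on all 6 arrays, the probes of each miRNA were summed, and values were set to a floor of 5.15 (1% of the percentile level or the lowest detected signal, whichever was lower) before taking log2. A miRNA was tested where it was detected on all arrays of at least 1 group, which left 449 of 758; 272 were detected on no array. The number of arrays limits the precision. The median SD between replicates was 0.12 on the log2 scale in both groups.

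Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, 4 residual degrees of freedom and 2.52 prior ones), with Benjamini-Hochberg adjustment over all tested miRNAs and a threshold of 0.05. The design, the 16 miRNA lists, the alternatives and the rule for named miRNAs were fixed before the data were examined. Exceptions among the alternatives were normexp on median signals and the arrays of header code 1 alone, chosen after seeing the data. Lists with at least 3 tested members were tested with limma's camera with a preset correlation of 0.01, adjusted over 15 lists, and 5 pairs of lists share members. The lists hold 144 miRNAs, of which 143 are on the array and 119 were tested. The rule names miRNAs past the threshold with non-overlapping groups, up to 15 in each direction, the miRNAs of the series title, up to 4 members per list by smallest p, and any tested member of the cardiomyocyte, leukocyte and inflammation lists. MiRNAs outside it are named as partner strands or were chosen after their values were seen. Different miRNAs were compared only by how their ratio differed between groups. Names are those of the array design. The files name build rn4, and miRNA genes were matched by name to a RefSeq table of another assembly, GRCr8, which held 415 of the 449 tested miRNAs and was used only for which genes neighbour each other.

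The same scaling, summing, floor and fit were run on simulated probe signals with the probe means and the spread of this comparison and 449 miRNAs tested. Detection calls were those of the real arrays, so the detection and filter steps were not tested. Spreads were dealt at random over miRNAs, and errors were drawn independently between miRNAs. The percentages below therefore do not account for a spread that depends on signal or for variation shared between miRNAs. As many miRNAs were set to rise as to fall, while in the data 8 were higher and 3 lower past the threshold. An unbalanced change is thus not covered by the percentages or the shifts below. With 24 miRNAs changed, 97.5% of 4-fold, 91.7% of 2-fold, 54.2% of 1.5-fold and 11.7% of 1.25-fold changes were recovered, and 5.56% of calls fell on unchanged miRNAs. The simulation also showed a limit of percentile scaling: unchanged miRNAs took a shared shift, from -0.06 to 0.06 on the log2 scale over 20 sets with 0 miRNAs changed, from -0.06 to 0.12 with 24 changed, and from -0.14 to 0.08, with a mean of -0.06, with 80 changed.

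Alternatives were other scalings (75th percentile over all probes, median, quantile, none), other ways to combine probes (brightest probe, mean of log2 values, software total signal), the authors' processed values, other filters and floors, eBayes with trend and robust settings, the replicate number or the array code as a block, a fold threshold, camera with an estimated correlation, limma's fry, the software's detection flag and leaving out each sample. The normexp background correction with an offset of 50 was planned on the mean spot signals, which the files used here do not hold, and ran on the median signals instead. The 2 spike-in metrics, of 9 quality metrics in the headers, lay outside the software's range on all 6 arrays. The array header codes used here are the first of 2 numbers. In sample order, the second ran from 1 to 4 under code 1 and from 1 to 2 under code 2. The headers do not state whether the codes mark a slide or a position, but arrays of both codes shared a scan.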

Results

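MicroRNAs were measured in left ventricular myocardium of male rats on 6 single-colour microarrays, 1 array per sample. Of these, 3 samples came from control rats that had the same operation without ligation of the artery, and 3 came from rats taken 24 h after ligation of the left coronary artery, which stops blood flow to part of the left ventricle and causes a myocardial infarction (MI). The control samples carry a time of 0 h in their labels, so time after surgery and ligation cannot be separated. The labels give the time only, and the group of each sample was read from that time together with the description of the operation. The series design speaks of rats in each group, but no label ties a sample to its own animal, so the p-values measure the spread between these samples. Each array carried probes for 758 miRNAs, of which 433 were detected on all 6 arrays. The arrays detected 458, 447 and 472 miRNAs in control replicates 1 to 3, and 446, 466 and 468 in MI replicates 1 to 3. The mean was 459 ± 12.5 (SD, n = 3) in controls and 460 ± 12.2 (SD, n = 3) after MI, and a two-sided exact permutation test gave p = 1, where the smallest p that 3 against 3 samples allow is 0.1.

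The main comparison asked which miRNAs differed in the ventricle 24 h after coronary ligation. Both mature strands of the miR-21 precursor were higher after MI: miR-21-3p rose 4.00-fold and miR-21-5p, the guide strand and a miRNA known to be induced in injured heart, rose 2.04-fold. The rise of miR-146b-5p, a miRNA induced by inflammatory signalling, was 3.47-fold. MiR-490-5p rose 2.01-fold, and miR-132-3p, induced by growth and inflammatory signals, and miR-18a-5p rose 1.81-fold and 1.70-fold (n = 3 per group). Among the lower miRNAs, miR-181b-1-3p was 1.54-fold, miR-342-5p 1.38-fold and miR-30b-3p 1.30-fold lower after MI. Of the 3 MI arrays, miR-181b-1-3p was well above background on 2 and miR-342-5p on 1, so these folds are uncertain.

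In limma with Benjamini-Hochberg adjustment over the 449 miRNAs tested, 8 miRNAs were higher and 3 were lower after MI at an adjusted p under 0.05. With the 75th percentile taken over all probes instead of the detected ones, the split was 5 higher and 5 lower, and with quantile normalization it was 5 higher and 4 lower. An unadjusted p under 0.05 was reached by 61 miRNAs, 38 higher and 23 lower, where chance alone gives 22.45. The values of the 2 groups did not overlap for 93 miRNAs (20.7%), where chance gives 10%. Of the 11 miRNAs past the threshold, 4 differed by at least 2-fold. All 11 had non-overlapping groups. Without control replicate 1, 2 or 3, limma called 5 higher and 0 lower miRNAs each time, with 64, 36 and 55 at an unadjusted p under 0.05. Without MI replicate 1, 2 or 3 it called 11 and 1, 4 and 0, and 9 and 1, with 56, 68 and 51 at an unadjusted p under 0.05. MiR-146b-5p, miR-21-5p, miR-21-3p and miR-18a-5p passed in all 6 of these fits, and miR-490-5p in 5, missing without MI replicate 2 (limma adjusted p = 0.0553; 0.00365 to 0.134 over its alternatives). MiR-132-3p and miR-503-5p passed only without MI replicate 1, miR-7a-5p only without MI replicate 3, miR-181b-1-3p without MI replicate 1 or 3, and miR-342-5p and miR-30b-3p in none.

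The log2 fold change of miR-21-3p was 2.00 ± 0.19 (SE; limma adjusted p = 0.00356, n = 3 per group), with control arrays between 4.98 and 5.56 and MI arrays between 7.10 and 7.60 on the log2 signal scale. Over the alternatives it ranged from 0.56 to 2.31, and of its 4 probes 1 was well above background on 6 arrays, 1 on 4 and 2 on 3. MiR-146b-5p changed by 1.79 ± 0.14 (limma adjusted p = 0.00209), from a mean of 8.48 ± 0.05 (SD) in controls to 10.27 ± 0.28 (SD) after MI. MiR-21-5p changed by 1.03 ± 0.08 (limma adjusted p = 0.00209), from 13.62 ± 0.08 (SD) to 14.65 ± 0.10 (SD). For miR-490-5p the change was 1.00 ± 0.11 (limma adjusted p = 0.00665), while its partner strand miR-490-3p differed by 0.06 ± 0.10 and took the opposite sign under 3 of the other scalings. The difference of miR-132-3p was 0.85 ± 0.14 (limma adjusted p = 0.0332), and that of miR-18a-5p 0.77 ± 0.08 (limma adjusted p = 0.00356). Smaller rises were those of miR-7a-5p, 0.54 ± 0.09, and miR-503-5p, 0.50 ± 0.09, with limma adjusted p of 0.0332 and 0.0401. Among the lower miRNAs, miR-181b-1-3p had a log2 fold change of -0.63 ± 0.09 (limma adjusted p = 0.0215), and it was well above background on 3 control arrays and 2 MI arrays. MiR-342-5p, at -0.47 ± 0.08, was well above background on 3 control arrays and 1 MI array, and miR-30b-3p, at -0.38 ± 0.06, on all 6 arrays; both had a limma adjusted p of 0.0332. The direction of miR-342-5p was the opposite in the authors' processed values, at 0.75, and after normexp background correction, which adds an offset of 50 and was run on median signals after seeing the data, at 0.02. With normexp, miR-181b-1-3p stood at -0.04 (limma adjusted p = 0.691; 0.00103 to 0.691 over its alternatives) and miR-30b-3p at -0.18, and with a floor 4 times as high miR-181b-1-3p stood at -0.34, while it reached -1.19 in the software total signal. With normexp, miR-21-3p, miR-490-5p, miR-18a-5p and miR-132-3p stood at 0.56, 0.55, 0.50 and 0.38.

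**Figure D1:**
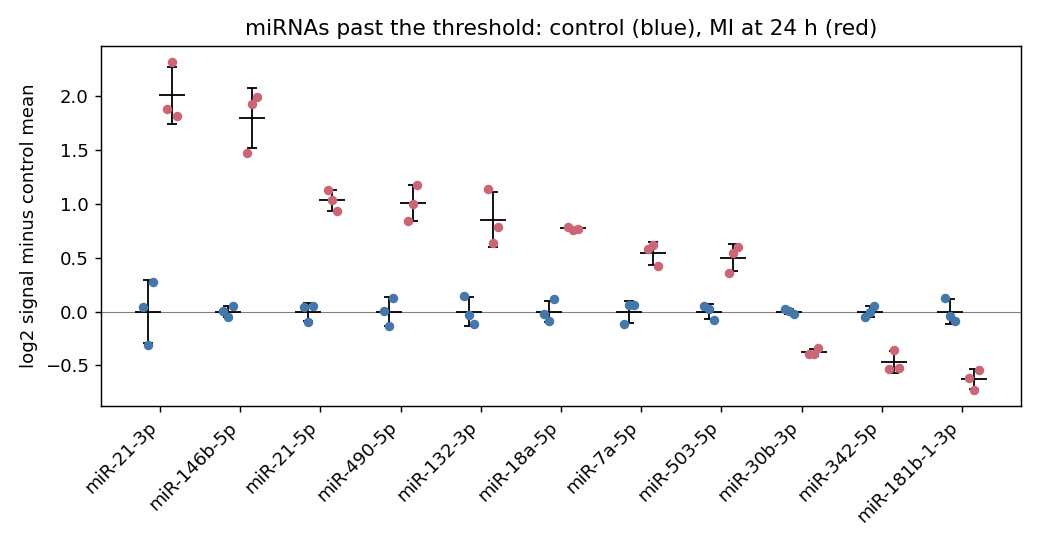
Log2 signal of the 11 miRNAs past the threshold, each minus its control mean, on the vertical axis, with miRNAs along the horizontal axis. Points are single arrays (blue, 3 control; red, 3 MI at 24 h), and horizontal marks with bars are group means with SD; the MI points of miR-21-3p and miR-146b-5p lie farthest from the controls, with mean differences of 2.00 and 1.79.

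The arrays carry header codes of 2 kinds, with the 3 controls and MI replicate 1 under code 1 and MI replicates 2 and 3 under code 2. With the code as a block, 3 miRNAs were higher in limma with Benjamini-Hochberg adjustment (miR-146b-5p, miR-21-5p and miR-132-3p) and 0 were lower, with 47 at an unadjusted p under 0.05. Their log2 fold changes were 1.47, 1.12 and 1.13 in that fit; miR-21-3p, miR-18a-5p and miR-490-5p stood at 1.88, 0.79 and 0.84. Within the 4 arrays of code 1, chosen for comparison after seeing the data, the log2 fold change of miR-146b-5p was 1.47 (limma adjusted p = 0.0212; 0.000357 to 0.0386 over its alternatives). There it was 1.12 for miR-21-5p and 1.88 for miR-21-3p, each with a limma adjusted p of 0.0530, against ranges of 0.000629 to 0.0530 and 0.00188 to 0.0626 over the alternatives. The lone MI sample of code 1 was taken to vary as the controls do. Code 2 holds MI samples only and gave no value of its own, so the fit with the code as a block also rests on MI replicate 1 against the 3 controls. Control replicate 3 came from a scan of its own, and the other arrays, of both codes, shared a scan.

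The series title names miR-146b-5p and miR-222-5p, which the study chose with the help of these samples, so their direction here is not independent evidence. Adjusted over all miRNAs, 1 of the 2 was past the threshold, and adjusted over the list alone 2 of 2 were. MiR-222-5p was not well above background on any control array and was well above it on all 3 MI arrays. The scanner software's own flag marked it as detected on 2 of 3 control arrays, replicates 1 and 3, and on all 3 MI arrays. Its log2 signal was 3.29 ± 0.53 (SD, n = 3) in controls and 4.37 ± 0.30 (SD, n = 3) after MI, a difference of 1.08 ± 0.28 (SE; limma adjusted p = 0.178). As a bound for the undetected controls, the MI mean was 1.95-fold the control mean, a log2 difference of 0.96. That bound sets the MI mean against the control mean of, per array, the higher of the lowest detected signal and the measured one. It does not allow for the spread between samples, so a smaller rise is not excluded. Without single samples the measured log2 fold change ranged from 0.78 to 1.26. In the authors' processed values the difference was 4.13, and in the total signal of the scanner software it was 2.00 (limma adjusted p = 0.04345; 0.04345 to 0.641 over its alternatives). Of its 2 probes, 1 was well above background on 3 arrays and the other on 0. MiR-222-3p, the guide strand of the same precursor, differed by 0.04 ± 0.07, with a sign that turned under 3 of the other scalings.

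Of the list of miRNAs induced by inflammation, 4 of 10 tested members rose adjusted over all miRNAs: miR-146b-5p, miR-21-5p, miR-21-3p and miR-132-3p. Adjusted over the list alone, 5 were higher, with miR-223-3p added, and 1 was lower, miR-146a-5p, a close relative of miR-146b that restrains the same signalling. MiR-146a-5p had a log2 fold change of -0.29 ± 0.08 (limma adjusted p over all miRNAs = 0.194). MiR-155-5p, a miRNA of activated immune cells, stood at 0.19 ± 0.10, and miR-212-3p, made from the same gene region as miR-132, at -0.03 ± 0.11, with the opposite sign after quantile normalization. The list holds miR-146b-5p, which the study chose with the help of these samples, and both strands of miR-21. Its shift is therefore not wholly independent evidence. The list as a whole shifted up by a mean log2 fold change of 0.77 (limma's camera with a preset correlation, adjusted p = 0.000379). That call was lost when camera was set to estimate the correlation from the data (camera adjusted p = 0.225 with an estimated correlation). The estimate was 0.0104, close to the preset 0.01, so the size of the correlation does not account for the loss. With the array code as a block, which rests on MI replicate 1 alone, and the preset correlation, the list's adjusted p in camera was 3.7e-05.

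The leukocyte list held 10 tested members, and adjusted over all miRNAs 1 was higher (miR-146b-5p) and 1 lower (miR-342-5p). Adjusted over the list alone, 2 were higher and 2 lower. MiR-223-3p, abundant in neutrophils and other myeloid cells, had a log2 fold change of 1.45 ± 0.29 (limma adjusted p = 0.0619), with MI arrays at 11.64, 12.84 and 12.51 against controls between 10.81 and 10.95. Without MI replicate 1 its adjusted p in limma was 0.00473, with trend and robust settings it was 0.0448, and over all alternatives it lay between 0.00473 and 0.241. With the array code as a block its log2 fold change was 0.76. MiR-142-3p, expressed across blood cell lineages, stood at 0.21 ± 0.12, and at -0.01 with the array code as a block. The lymphocyte miRNAs miR-150-5p and miR-342-3p stood at -0.21 ± 0.09 and -0.17 ± 0.07. The mean of the list was 0.25, its median 0.02, and the direction of camera's test was down (adjusted p = 0.906), so mean and test differed in sign.

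The cardiomyocyte list covers miRNAs of heart and skeletal muscle. None of its 14 tested members was past the threshold in limma adjusted over all miRNAs; adjusted over the list alone 0 were higher and 1 was lower, and at an unadjusted p under 0.05 it was 0 and 2. That member was miR-133a-5p, at -0.40 ± 0.08 (limma adjusted p over all miRNAs = 0.0619). It passed the threshold over all miRNAs in 5 alternatives: normexp (limma adjusted p = 0.0170), trend and robust settings (0.0318), the software total signal (0.0440), median scaling (0.0456) and the 75th percentile over all probes (0.0498), with 0.0170 to 0.448 over all alternatives. The abundant muscle miRNAs miR-1-3p, miR-133a-3p and miR-499-5p stood at -0.02 ± 0.08, -0.10 ± 0.09 and -0.07 ± 0.11, and miR-1-3p changed sign with the array code as a block. MiR-208a-3p, encoded in a cardiac myosin gene, stood at -0.21 ± 0.08. The list's adjusted p in camera was 0.232, and 0.0364 without control replicate 3 (0.0364 to 0.949 over its alternatives).

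In the miR-17-92 family, named for a cluster active in dividing cells, 1 of 12 tested members rose adjusted over all miRNAs (miR-18a-5p), and 2 were higher adjusted over the list alone, with miR-17-5p added at 0.36 ± 0.07. Over all miRNAs, miR-17-5p had a limma adjusted p of 0.0619, of 0.0195 with normexp and of 0.0448 with trend and robust settings (0.0195 to 0.403 over its alternatives). MiR-20a-5p, miR-20b-5p and miR-19a-3p had log2 fold changes of 0.27 ± 0.09, 0.28 ± 0.09 and 0.22 ± 0.08. The list shifted up, with 11 of 12 members above 0 and a mean of 0.22 (limma's camera adjusted p = 0.000912). The call did not hold in the same test with a free correlation (adjusted p = 0.668 with an estimated correlation). With the array code as a block, resting on MI replicate 1 alone, and the preset correlation, it was 0.00128.

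Of the miR-30 family, abundant in heart, 0 of 9 tested list members were past the threshold, adjusted over all miRNAs or adjusted over the list alone, with 4 lower in limma at an unadjusted p under 0.05, and 9 of 9 lay below 0. MiR-30d-3p, miR-30e-5p, miR-30d-5p and miR-30a-5p had log2 fold changes of -0.23 ± 0.07, -0.20 ± 0.07, -0.18 ± 0.06 and -0.16 ± 0.07. The list shifted down, with a mean of -0.15 (limma's camera adjusted p = 0.000274). This was not a call when the correlation was estimated (adjusted p = 0.668 with an estimated correlation), and with the array code as a block, resting on MI replicate 1 alone, and the preset correlation, it was 0.0125. MiR-30d-3p was past the threshold over all miRNAs with quantile normalization (-0.29, limma adjusted p = 0.0208; 0.0208 to 0.495 over its alternatives). MiR-30b-3p, which fell, is not a member of the list as fixed.

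**Figure D2:**
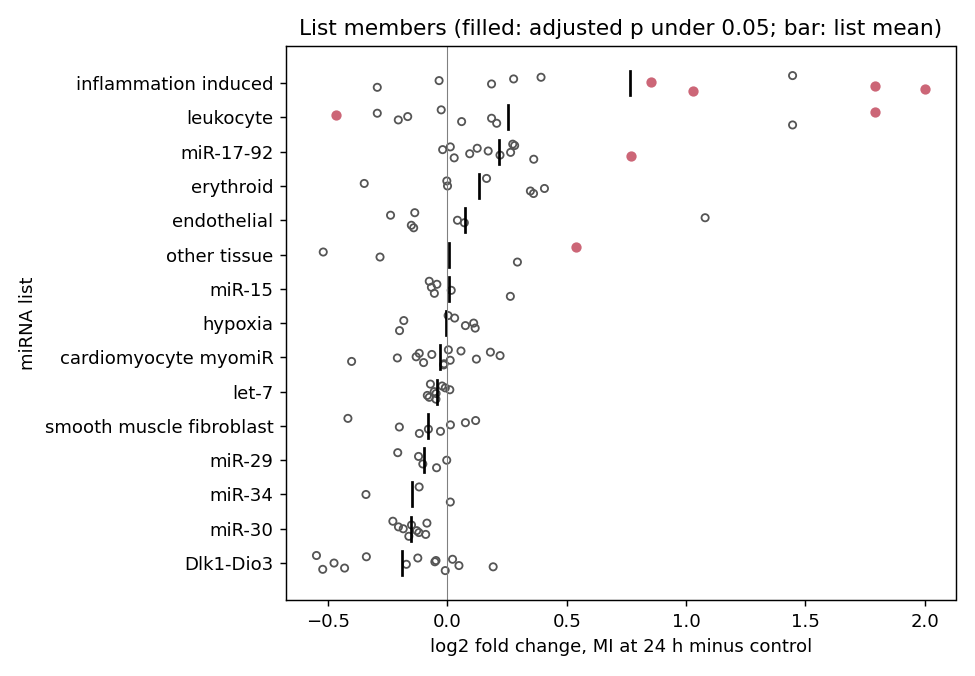
Log2 fold change (MI at 24 h minus control) of each tested member, horizontal axis, by miRNA list, vertical axis. Filled points have a limma adjusted p under 0.05 over all miRNAs, open points do not, and vertical bars are list means, which run from -0.19 in the Dlk1-Dio3 list to 0.77 in the list of miRNAs induced by inflammation. The list of the series title is not drawn.

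The other lists had 1 call between them adjusted over all miRNAs. In the list of miRNAs typical of other tissues, 1 of 4 tested members rose (miR-7a-5p, abundant in endocrine and neural tissue), adjusted over all miRNAs and adjusted over the list alone. The erythroid list had 0 of 7 past the threshold on either adjustment, with miR-451-5p and miR-144-3p, both abundant in red blood cells, at 0.36 ± 0.18 and 0.35 ± 0.21. The endothelial list had 0 of 7, with miR-126a-3p and miR-126a-5p at -0.14 ± 0.08 and -0.15 ± 0.09, a mean of 0.08, a median of -0.14 and a camera direction of down. The smooth muscle and fibroblast list had 0 of 8 (miR-10b-5p at -0.42 ± 0.18), and the hypoxia list 0 of 7, with a mean of -0.01, a median of 0.03 and a camera direction of down. MiR-210-3p, the miRNA most tied to low oxygen, stood at -0.20 ± 0.10, and miR-26a-5p at -0.18 ± 0.07. The miR-29 list had 0 of 5 (miR-29c-5p at -0.21 ± 0.10), the miR-15 list 0 of 6 (miR-15b-5p at 0.26 ± 0.08) and the let-7 list 0 of 9. The miR-15 list had a mean of 0.01 and a median of -0.05, with a direction of down in camera and up in fry. The miR-34 list had 0 of 3 adjusted over all miRNAs and 1 lower adjusted over the list alone (miR-34b-5p, -0.34 ± 0.10). The Dlk1-Dio3 list, a large imprinted cluster, had 0 of 13, with miR-337-3p and miR-136-5p at -0.55 ± 0.33 and -0.52 ± 0.33. At an unadjusted p under 0.05 in limma, the endothelial and miR-15 lists had 1 higher member each, the hypoxia and miR-34 lists 1 lower member each, and the erythroid, smooth muscle and fibroblast, miR-29, let-7 and Dlk1-Dio3 lists 0. Camera's adjusted p values for these lists lay between 0.226 and 0.844, and the Dlk1-Dio3 list passed the threshold with the array code as a block (adjusted p = 0.0487), in the arrays of code 1 alone (0.0228), without control replicate 2 (0.0473) and without MI replicate 2 (0.0452), with 0.0228 to 0.668 over its alternatives.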

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

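The look at control features was chosen after seeing the data. Of the 22 control features, which the comparisons leave out, 11 were detected on all 6 arrays, and 2 of these had every MI array above every control array, where chance gives 5% of features; no difference was tested. After scaling, the feature named mr_1 was 1.33-fold higher after MI (1.328), from a mean log2 signal of 10.17 in controls to 10.57 after MI, with all 3 MI arrays above all 3 controls. The feature hur_6 was 1.14-fold higher (1.136), at 15.73 against 15.55, also with no overlap. The feature dmr_3 was detected on 2 arrays, MI replicates 1 and 2, and neither on MI replicate 3 nor on any control array. The files do not say what these features measure, and no biological explanation was tested. None of the 11 lay below all controls.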

How the results depend on the processing

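The tests with normexp on median signals and on the arrays of code 1 alone were chosen after seeing the data. The rise of miR-146b-5p was past the threshold in 23 of 23 other fits, that of miR-21-5p in 22, miR-18a-5p in 20, and miR-21-3p and miR-490-5p in 19 each; miR-132-3p passed in 10, miR-7a-5p in 8, miR-503-5p in 7, miR-30b-3p in 12 of 23, miR-181b-1-3p in 11 of 22 and miR-342-5p in 3 of 22. Of 1123 recomputed values of single named miRNAs, 982 kept direction and side of the threshold and 35 changed sign, 2 of these for a called miRNA. Of 15 list tests, 9 kept their side throughout. Except where stated, the cause of a change was not tested.

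Against 8 higher and 3 lower miRNAs, the counts were 5 and 5 with the 75th percentile over all probes, 5 higher with quantile normalization, 5 higher with the authors' processed values, 3 higher with no filter (758 tested), 5 and 1 with a floor 4 times as high, 1 lower with no scaling and 1 lower among miRNAs detected on all 6 arrays. A fold of at least 2 left 4 and 0, and an unadjusted p with a fold of at least 2 left 0 lower. The arrays of code 1 alone gave 1 and 0, the array code as a block 3 and 0 (51 and 47 at an unadjusted p under 0.05), with fewer samples or degrees of freedom. Leaving out each sample gave 4 (without MI replicate 2) to 11 (without MI replicate 1) higher and 0 to 1 lower, with 5 and 0 without each control. The count of higher members of the inflammation list, 4, was 2 with no filter, 1 in the arrays of code 1 alone and 3 to 5 without single samples.

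The replicate number as a block gave 3 higher and 0 lower miRNAs in limma (62 at an unadjusted p under 0.05), and 2 higher members of the inflammation list. Same-numbered samples deviated together with correlations of 0.12, -0.04 and 0.11 across miRNAs, so the numbers were not taken to pair the samples. By these deviations no sample correlated best with its own number in the other group. The highest correlations were 0.52 for control replicate 2 with MI replicate 1, 0.47 for control 3 with MI 2, and 0.35 for control 1 with MI 3.

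With an estimated correlation, camera's adjusted p was 0.225 for the inflammation list and 0.668 for the miR-17-92 and miR-30 lists; fry, which asks whether members move 1 way on balance and does not compare them with other miRNAs, gave 0.0121, 0.0419 and 0.0479. The Dlk1-Dio3 list passed with the array code as a block (0.0487) and in the arrays of code 1 alone (0.0228), both resting on MI replicate 1 alone, and ranged from 0.0452 to 0.4695 without single samples. The cardiomyocyte list ranged from 0.0364 (without control replicate 3) to 0.701, and the let-7 list passed with normexp (0.0397; up to 0.995 over its alternatives).

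Sign changes in the array code block and the arrays of code 1 alone were 0.0521 and 0.0512 for miR-1-3p, -0.00977 and -0.0107 for miR-142-3p, 0.0720 and 0.0710 for miR-212-3p, -0.0112 and -0.0121 for miR-222-3p, -0.1456 and -0.1465 for miR-31a-5p, -0.0403 and -0.0412 for miR-31a-3p, and -0.0404 and -0.0414 for miR-490-3p. With the 75th percentile over all probes, quantile normalization and no scaling, miR-222-3p stood at -0.0327, -0.0571 and -0.0268 and miR-490-3p at -0.0180, -0.0235 and -0.0121; miR-222-3p stood at -0.00647 in the software total signal. MiR-212-3p stood at 0.0534 with quantile normalization and 0.0533 in the authors' values, and miR-342-5p at 0.0187 with normexp and 0.752 in the authors' values. Without single samples the log2 fold change ranged from -0.0807 to 0.0430 for miR-1-3p, from -0.846 to 0.355 for miR-204-5p, from -0.120 to 0.0475 for miR-212-3p, from -0.5015 to 0.907 for miR-31a-5p, from -0.422 to 1.06 for miR-31a-3p and from -0.0423 to 0.108 for miR-490-3p.

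The planned normexp on mean signals was not run. By the software's own flag the arrays detected 9.33 fewer miRNAs after MI (a difference of -9.33; two-sided exact permutation p = 0.5), against a difference of 1 by the spots. Between 53.0% and 57.8% of spots were well above background, which limits what dim miRNAs such as miR-222-5p, miR-181b-1-3p and miR-342-5p can show.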

Other observations

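The tests of single miRNAs, of precursor strands and of gene neighbours below were chosen after seeing the data; the other splits of the samples were planned. MiR-31a-3p, miR-31a-5p and miR-204-5p, singled out after their values were seen, varied widely between samples of a group. MiR-31a-3p had log2 signals of 6.67, 4.75 and 7.72 in controls, a 7.81-fold range, and of 6.34, 6.98 and 6.996 after MI. MiR-31a-5p had log2 signals of 8.82, 6.97 and 9.78 in controls, a 7.04-fold range, and of 8.38, 9.01 and 9.02 after MI. MiR-204-5p had 8.43, 7.49 and 9.37 in controls and 6.53, 8.83 and 8.81 after MI. Among miRNAs not tested, miR-133b-5p, miR-365-5p and miR-449a-5p were detected on 2 MI arrays and 0 control arrays, and miR-3596c and miR-742-3p on 2 control arrays and 0 MI arrays.

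The real grouping gave 11 miRNAs past the threshold in limma, and the highest of the other splits of the 6 arrays gave 2. As large a count came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.

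In the authors' processed values, miR-222-5p stood at 1.17, -3.002 and -0.86 in controls and at 3.78, 2.89 and 3.02 after MI. Their log2 difference exceeded the one from measured signals, 1.08, by 3.05, but with no control array well above background the measured difference cannot exclude a larger one. The software's total signal was the fixed value of 0.1 in control replicate 2, but 3.69 and 3.09 in control replicates 1 and 3, where it was marked as detected and which stand at 1.17 and -0.86 in the authors' values. In the software's total signal, with a floor under low values, the log2 difference was 2.00. The authors' values follow the ranks of that signal, so their excess over 2.00 reflects processing, such as the fixed value and the quantile step. The 2.00 itself depends on the floor and scaling used here, so how much each step added cannot be told. Background left in the dim control signals may account for part of the rest. A rise of the size in the authors' values and a smaller one (limma adjusted p = 0.178) cannot be told apart here.

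MiR-223-3p stood at 1.45 ± 0.29 while miR-142-3p, found across blood cell lineages, stood at 0.21 ± 0.12. The log2 ratio of miR-142-3p to miR-223-3p differed between MI and control by -1.24 ± 0.25 (SE, n = 3; two-sided exact permutation p = 0.1, the smallest possible). The ratio restates the contrast of these miRNAs, which were picked after seeing the data, and is not further support. As it stands, that contrast argues against an equal increase of all leukocytes as the whole source. Entry of cells rich in miR-223 such as neutrophils may contribute. Of the other leukocyte members, 1 was higher at an unadjusted p under 0.05 in limma (miR-146b-5p). At the same threshold 2 were lower, miR-342-5p at -0.47 and miR-146a-5p at -0.29. MiR-146b-5p is also on the list of miRNAs induced by inflammation, so its rise cannot tell cell entry from induction. More miR-223 per cell, and the array code, with which as a block the difference was 0.76 and rested on MI replicate 1 alone, stay open.

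MiR-490-5p rose while miR-490-3p, of the same precursor, stood at 0.06 ± 0.10, with the opposite sign under 3 of the other scalings. A signal close to background is argued against by all 4 probes of both strands, which were well above background on 6 arrays, with each miR-490-5p probe higher on all 3 MI arrays than on any control. A scaling factor per array as the cause is argued against by the log2 ratio of the strands, in which it cancels and which differed by 0.947 ± 0.13 (SE; limma adjusted p over 114 precursors = 0.0501), and by miR-490-5p passing under all 4 other scalings at 0.93 to 0.97. With normexp on median signals the log2 fold change of miR-490-5p was 0.55. That setting also adds a constant offset, which by itself shrinks the log2 fold changes of dim miRNAs. The lower value therefore cannot tell whether the size of the rise depends on how background is handled. With the array code as a block, which rests on MI replicate 1 alone, the log2 fold change of miR-490-5p was 0.84, and the array code stays open. Binding of another RNA to these probes was not tested, since probe sequences were not used here.

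The hypothesis that both strands of a precursor shift together was tested over 114 pairs. The mean absolute difference between strands was 0.20, against 0.26 in random pairings (permutation p = 1e-05, the smallest the permutations can give), and Spearman's rho was 0.33 (permutation p = 0.00051), with 74 pairs (64.9%) of the same sign. MiRNAs are not independent replicates, unequal spread between miRNAs may lower the first p, which was not tested, and variation shared by the strands between samples gives the same pattern. Genes of tested miRNAs were also chained into groups where the next gene lay within 10 kb, so paired genes can lie farther apart. The 458 pairs within groups gave 0.23 against 0.26 (permutation p = 0.203), and without the largest group the permutation p was 0.296.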
